A study of Mus musculus with 4 samples.

How the data were processed

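RNA from 4 samples of a stable NIH3T3 clone was measured on Affymetrix arrays, 2 grown with doxycycline (control) and 2 without it (Ctcfl). Per the labels, total RNA was extracted with a column kit and biotin-labelled. The deposited log2 values are RMA expression values that the authors made with the Expression Console software, per the labels. RMA corrects the background, quantile-normalises the arrays against each other and summarises the probes of a probe set on the log2 scale. The software version and settings were not given in the sources used here. The values carry 2 decimals, and the median was 5.20 to 5.24 on each array. No detection calls were used, so a low value cannot be separated from background.

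The table held 35512 probe sets, of which 1 had no value. Names came from the platform annotation of 2016: 21789 probe sets had 1 gene symbol, 1621 had several and 12101 are not listed there, so they are unnamed here and can include control probe sets. Symbols were checked through gene identifiers against the RefSeq table of GRCm38.p6, where 21698 probe sets matched and 0 symbols changed. That table also gave the positions used for the order of genes, for distances up to 100 kb and for genes that lie inside others. Each gene was represented by its probe set with the highest mean, which mattered for 999 genes with more than 1 probe set, and this left 19938 genes. No filter on dim genes was applied.

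Ctcfl and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 arrays per group, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The estimated prior had 4.21 degrees of freedom. The 31 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. A list with at least 5 measured members was tested with camera at a preset correlation of 0.01, adjusted over the lists, with the counts of members past the threshold over all genes and adjusted over the list alone. camera with an estimated correlation, camera on ranks and fry were alternatives. For the intensity trend with robust variances, the lists were tested with cameraPR on the statistics of that fit. Other alternatives were quantile normalisation of the values, median centring, leaving out the dimmest 33.3% of genes, the mean of a gene's probe sets, an intensity trend with robust variances (statmod 1.5.0), a replicate block, each array left out, ordinary t statistics and a minimum of 1.5-fold. Neighbouring genes were compared with 10000 random draws. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

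The genes named were Ctcfl and Ctcf, then up to 12 per direction with the largest log2 change among genes past the threshold with non-overlapping groups. Predicted genes, clones, olfactory, vomeronasal and microRNA genes were passed over, and places left were filled by the smallest unadjusted p. From each list, up to 4 members past the threshold were added, or the 2 with the smallest unadjusted p where none passed. Members past the threshold over their list alone, relatives of Gstm5 and Akr1c18, neighbouring genes and the other list members given with values were chosen after their values were seen.

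The test was tried on simulated data with the means of the 19938 genes and with variances drawn at random from the estimated prior. There were 200 changed genes in each of 20 simulations of 2 against 2 arrays. The test recovered 98.7% of genes changed by 2 on the log2 scale, 85.7% of those changed by 1 and 6.12% of those changed by 0.5. Of its calls, 4.27% were false. Such variances follow the model that the test assumes, so these rates do not show how it performs on the real variances. The adjustment also grows looser with more changed genes. In the data only 9 genes passed, so the recovery rates can be too high for them. A shift of -0.3 in a list of 20 independent genes was called in 20 of 20 simulations. The cholesterol synthesis list had an estimated correlation of 0.58 between members, so this does not show how camera performs on correlated members.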

Results

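The series measured messenger RNA in NIH3T3 cells, an established line of mouse fibroblasts, that carried a stably integrated vector for FLAG-tagged mouse Ctcfl. Ctcfl encodes CTCFL, also called BORIS, a testis-expressed paralog of the insulator-binding protein CTCF. In this Tet-Off system doxycycline is used to repress the transgene. The 2 control samples were grown with 2 µg/ml doxycycline, and the 2 Ctcfl samples were grown for 48 h in medium without it, so presence of the drug and absence of Ctcfl induction always coincided. Each sample was hybridised to an Affymetrix array, which gave values for 35511 probe sets and 19938 named genes. Across genes the Pearson correlation was 0.997 between the control arrays and 0.996 between the Ctcfl arrays, against 0.995 across groups. The first principal component held 45.8% of the variance between arrays and separated the groups. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical, and their small number limits the precision.

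The comparison of Ctcfl with control arrays asked which genes change when Ctcfl is expressed in fibroblasts. Ctcfl itself rose from 7.74 ± 0.04 to 10.36 ± 0.01 (log2, SD, n = 2 per group), a 6.15-fold increase (log2 change 2.62, SE 0.08, adjusted p = 5.38e-04 by limma). Whether its probe set lies in the part of the gene that the vector carries was not known, nor whether the control level, above the upper quartile of probe sets on both control arrays, reflects leaky expression or probe background. Its paralog Ctcf had a log2 change of -0.16 (SE 0.08, adjusted p = 0.537) and did not pass. In all, 9 genes passed, 6 higher and 3 lower in the Ctcfl arrays. The largest rise belonged to Adgrg1, an adhesion G protein-coupled receptor also called GPR56, which went from 4.66 ± 0.21 to 8.29 ± 0.07, or 12.3-fold (log2 change 3.62, SE 0.12, adjusted p = 5.38e-04). Gstm5, a mu-class glutathione S-transferase, rose 6.80-fold, from 7.91 ± 0.07 to 10.68 ± 0.12 (log2 change 2.76, SE 0.10, adjusted p = 6.02e-04). Lpcat2, a lysophospholipid acyltransferase that can make platelet-activating factor, rose 4.47-fold from 5.14 ± 0.14 to 7.30 ± 0.06 (SE 0.10, adjusted p = 0.00248). Col5a2, which encodes a chain of type V collagen, rose 2.56-fold from 8.74 ± 0.05 (SE 0.08, adjusted p = 0.0105). Slc29a3, a nucleoside transporter of lysosomes, rose 2.17-fold from 6.68 ± 0.11 to 7.80 ± 0.02 (SE 0.09, adjusted p = 0.0371).

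Of the genes that fell, Akr1c18, the 20-alpha-hydroxysteroid dehydrogenase that inactivates progesterone, decreased by 1.24 on the log2 scale to 8.76 ± 0.01 (SE 0.08, 2.36-fold lower, adjusted p = 0.0146). Hgf, the growth factor ligand of the Met receptor, fell by 1.13 (SE 0.09, 2.20-fold lower, adjusted p = 0.0275). Igfbp4, a secreted binding protein of insulin-like growth factors, fell by 0.94 (SE 0.08, 1.93-fold lower), and its adjusted p of 0.0499 lay at the threshold. For each of the 9 genes, both Ctcfl arrays lay on one side of both control arrays. Other mu-class glutathione S-transferase genes had smaller values than Gstm5, with log2 changes of 0.36 for Gstm7, 0.26 for Gstm6, 0.14 for Gstm2, 0.07 for Gstm4, -0.05 for Gstm3 and -0.06 for Gstm1, none of which passed. Near relatives of Akr1c18 had log2 changes of -0.23 (Akr1c13), 0.02 (Akr1c12), 0.08 (Akr1c14) and 0.36 (Akr1c6), and none of these passed either.

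**Figure D1:**
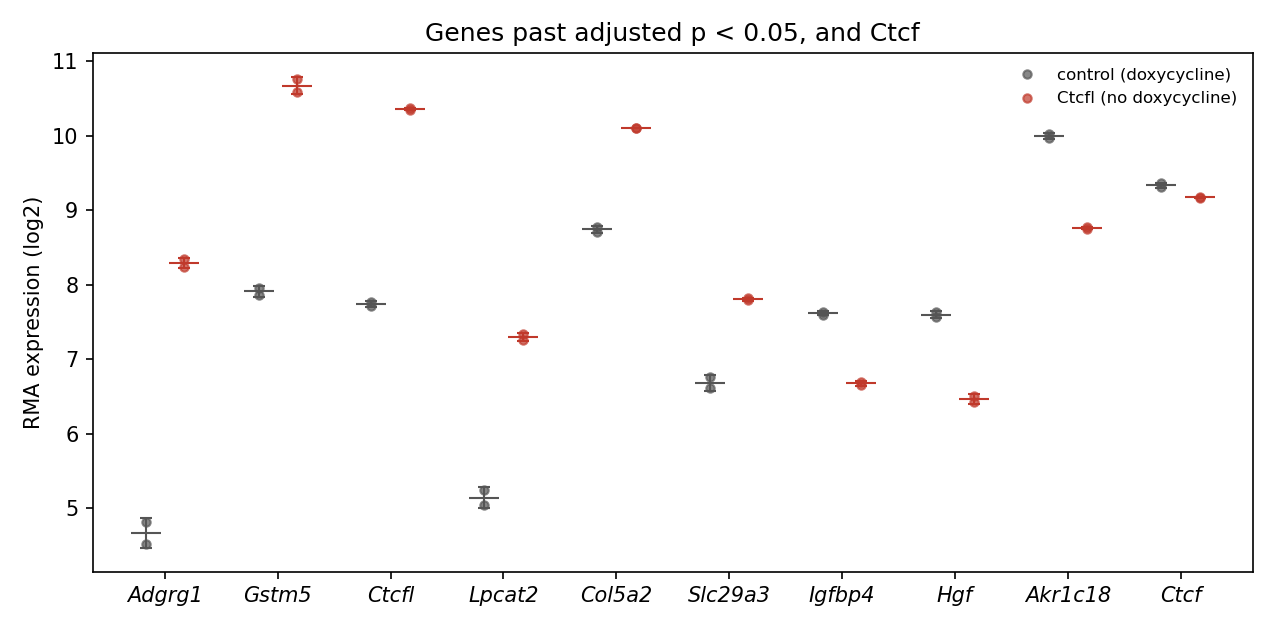
RMA expression (log2, y axis) of the 9 genes past the threshold and of Ctcf (x axis), with a point for each array, a horizontal line at each group mean and bars of 1 SD (n = 2 per group). Grey points are control arrays and red points are Ctcfl arrays; Adgrg1 shows the widest gap, from 4.66 to 8.29, and Ctcf a gap of -0.16.

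Genes next in order did not pass but had sizeable values. Among those higher in the Ctcfl arrays, Capns2, a small subunit of calpain, had a log2 change of 1.31 (SE 0.12, adjusted p = 0.0554), and Rab29, a small GTPase, had 1.10 (SE 0.11, adjusted p = 0.0780). Fam234a (0.82), Ifnz (0.82, an interferon gene), Fam20a (0.81) and Ermp1 (0.76) had adjusted p-values from 0.0780 to 0.0791. Among those lower, Cck, the precursor of the peptide hormone cholecystokinin, had -0.88 (SE 0.08, adjusted p = 0.0603) and Dcn, the matrix proteoglycan decorin, had -0.91 (SE 0.09, adjusted p = 0.0657). The log2 changes were -0.88 for Cytip and -0.83 for the glutamate transporter Slc1a3 and Gcnt4 was 1.99-fold lower, with adjusted p-values from 0.0780 to 0.0988. The AMPA receptor subunit Gria1 (-0.77), the metallothionein Mt2 (-0.98), the oncostatin M receptor Osmr (-0.78) and the pyruvate dehydrogenase kinase Pdk4 (-0.70) had adjusted p-values from 0.114 to 0.115.

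Across all genes, 91.2% differed by at most 1.2-fold between the groups. A change of at least 1.5-fold was measured for 88 genes, 47 higher and 41 lower, against 9 and 12 genes in the other 2 divisions of the arrays into pairs. Of all genes, 41.1% had non-overlapping groups, where chance gives 33.3% in either direction. At an unadjusted p under 0.05 there were 2129 genes (10.7%), 1069 higher and 1060 lower, against 523 and 938 genes in those divisions, where no gene passed after adjustment. There, a difference between the groups counts as spread within each pair and lowers the number of small p-values. The counts by p-value in those divisions therefore do not show what chance gives. The number of calls differed between alternatives: limma called 479 genes with an intensity trend and robust variances and 20 without the dimmest 33.3% of genes, but 0 (1940 unadjusted) with ordinary t statistics and 0 (1329 to 1663 unadjusted) when any array was left out. Ordinary t statistics rest on only 2 residual degrees of freedom, where a call over so many genes is hardly possible. Ctcfl itself had an adjusted p of 0.424 by that test. No probe set passed in a fit over all 35511 probe sets (1419 unadjusted with 1 gene symbol, 1345 with several or none). There Ctcfl had an adjusted p of 0.0660 by limma.

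**Figure D2:**
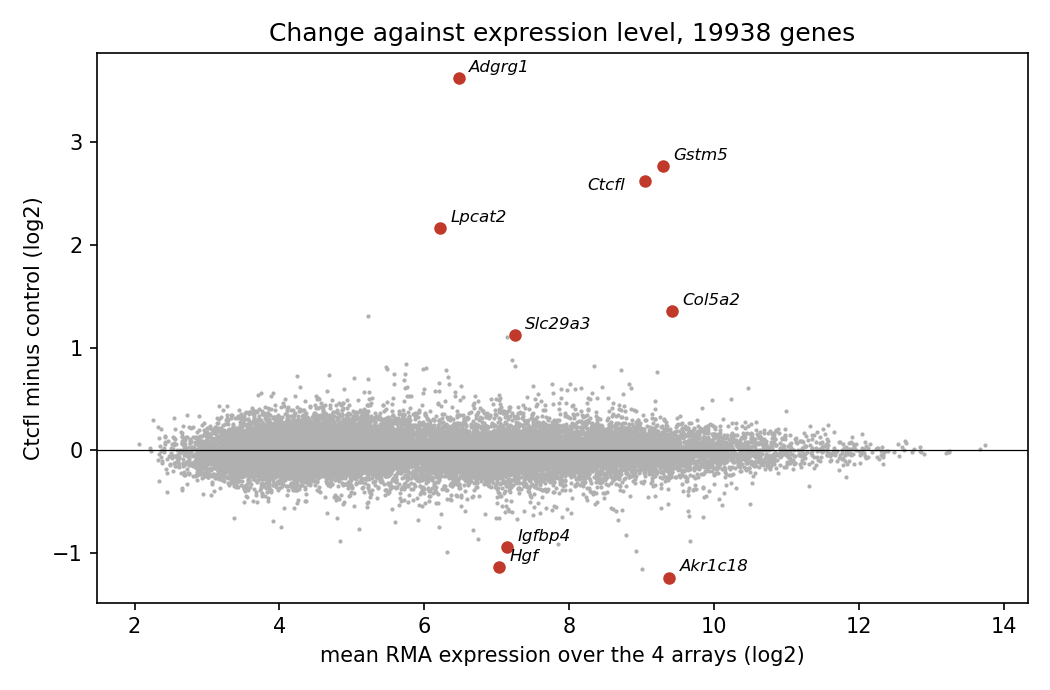
Log2 difference of Ctcfl minus control arrays (y axis) against mean RMA expression over the 4 arrays (log2, x axis) for the 19938 genes tested, with the 9 genes past the threshold in red. Most genes lie close to 0, and Adgrg1, Gstm5, Ctcfl and Lpcat2 lie at log2 changes of 3.62, 2.76, 2.62 and 2.16.

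Of the 31 gene lists, 6 were shifted lower and 1 was shifted higher relative to other genes by camera with a preset correlation. With a correlation estimated for each list, 0 were called (2 unadjusted). That version takes its p-values from only 2 residual degrees of freedom, where a list can hardly pass whatever its correlation. Its adjusted p-values therefore do not show that correlation between members removed the shifts. By camera with the preset correlation, the clearest shift was in cholesterol synthesis. With an estimated correlation, its unadjusted camera p was 0.121, against 0.0162 for the integrated stress response and 0.0298 for replication-dependent histones. All 20 measured cholesterol synthesis members had lower values in the Ctcfl arrays, 19 of them in both arrays against both controls. Their median log2 change was -0.38 (camera adjusted p = 4.50e-15, and adjusted p = 0.782 with an estimated correlation, which was 0.58 between members). No member passed over all genes, while 16 fell when adjusted over the list alone. Fdft1, the squalene synthase, had the largest change, -0.68 (SE 0.09, adjusted p = 0.115 over all genes). Cyp51, the lanosterol demethylase, had -0.56 (SE 0.11), the mevalonate pathway enzymes Mvd and Hmgcs1 had -0.55 (SE 0.11) and -0.52 (SE 0.10), and the sterol sensor Insig1 had -0.48 (SE 0.11). The transcription factor Srebf2, which drives this pathway, had -0.13 and did not pass.

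Genes of the integrated stress response, which are activated by the transcription factor ATF4, shifted lower. Of 30 measured members 27 had lower values, 24 of them in both Ctcfl arrays against both controls. The list's median was -0.18 (camera adjusted p = 1.39e-10, and adjusted p = 0.461 with an estimated correlation). That estimate was -0.026, below the preset 0.01, so correlation between members does not account for the larger p. No member passed over all genes, and 7 fell when adjusted over the list alone. These were the cystathionine gamma-lyase gene Cth (-0.64, SE 0.11), the alanine transaminase gene Gpt2 (-0.58, SE 0.09), the cystine transporter gene Slc7a11 (-0.46, SE 0.09), Stc2 (-0.46, SE 0.10), the mitochondrial serine hydroxymethyltransferase gene Shmt2 (-0.40, SE 0.10), Pck2 (-0.39, SE 0.09) and Atf5 (-0.33, SE 0.09). Atf4 itself had -0.18, Ddit3 -0.20 and Asns -0.11, and none of these passed.

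Among other metabolic and stress lists, nuclear-encoded respiratory chain genes shifted lower by a small amount. Of 36 measured members 29 had lower values, with a median of -0.08 (camera adjusted p = 0.00725, and adjusted p = 0.782 with an estimated correlation). No member passed over all genes or adjusted over the list alone, and 4 were lower at an unadjusted p under 0.05, among them the succinate dehydrogenase subunit Sdhb (-0.40, SE 0.09) and the ATP synthase subunit Atp5o (-0.23, SE 0.08). The list's adjusted p was 0.119 without control replicate 1. Mitochondrial ribosome genes did not pass (38 members, median -0.05, adjusted p = 0.395), with Mrps18a at -0.23 and Mrpl15 at -0.19. ER chaperones and unfolded protein response genes did not pass (22 members, median 0.01, adjusted p = 0.597), with Sdf2l1 at 0.45 and Herpud1 at -0.42. Glycolysis and hypoxia genes did not pass (27 members, adjusted p = 0.929), and their median of -0.03 and mean of 0.01 differed in sign, with the test on the side of the median. In that list Adm, the vasodilator peptide adrenomedullin, rose when adjusted over the list alone (0.78, SE 0.10), while Vegfa had -0.38. Cytosolic ribosomal protein genes did not pass (27 members, median -0.04, adjusted p = 0.17), with Rpl14 at -0.22 and Rpl30 at -0.14, but the list passed without control replicate 2 (adjusted p = 0.0192) and with an intensity trend and robust variances.

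Histone genes whose expression is coupled to DNA replication shifted lower. Of 19 measured members 17 had lower values, 14 of them in both Ctcfl arrays against both controls. The list's median was -0.19 (camera adjusted p = 1.91e-06, and adjusted p = 0.461 with an estimated correlation). Here too the estimate, -0.050, lay below the preset 0.01. No member passed over all genes. H4c3 (-0.54, SE 0.11), the linker histone gene H1f2 (-0.54, SE 0.09) and H2bc8 (-0.34, SE 0.08) fell when adjusted over the list alone. G1/S and DNA replication genes also shifted lower, though by little. Of 36 measured members 32 had lower values and 3 higher, with a median of -0.06 (camera adjusted p = 0.0133, and adjusted p = 0.782 with an estimated correlation). No member passed over all genes or adjusted over the list alone, and 1 was lower at an unadjusted p under 0.05, Uhrf1 (-0.22, SE 0.08), next to Chaf1b (-0.20, SE 0.08). This list's mean minus that of other genes was -0.077 over all arrays, -0.112 without control replicate 2 and -0.096 without Ctcfl replicate 2. It was -0.042 without control replicate 1 and -0.058 without Ctcfl replicate 1, where the list lost its call. G2/M and mitosis genes did not pass (39 members, median 0.04, adjusted p = 0.516), with Psrc1 at -0.32 and Dlgap5 at 0.22, but the list passed without Ctcfl replicate 1 (adjusted p = 0.0296).

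Fibroblast matrix genes moved in both directions. Of 36 measured members 22 had lower and 14 higher values, and the list shifted lower, with a median of -0.06 (camera adjusted p = 0.00725, and adjusted p = 0.782 with an estimated correlation). Col5a2 rose over all genes. Adjusted over the list alone, 8 members fell: Dcn (-0.91), the thrombospondins Thbs1 (-0.64) and Thbs2 (-0.54), the collagen genes Col6a3 (-0.62) and Col3a1 (-0.38), the growth factor receptor Pdgfrb (-0.56), the metalloproteinase inhibitor Timp3 (-0.52) and tenascin C, Tnc (-0.40), with standard errors of 0.09 except for Col6a3 (SE 0.12). The list's mean minus that of other genes was -0.106 over all arrays, -0.131 without control replicate 2 and -0.122 without Ctcfl replicate 1. It was -0.081 without control replicate 1 and -0.090 without Ctcfl replicate 2, where the list lost its call. Camera on ranks did not call it either. Contractile genes and targets of SRF and YAP, factors that respond to the actin cytoskeleton and tension, shifted higher. Of 24 measured members 21 had higher values, with a median of 0.08 (camera adjusted p = 0.0151, and adjusted p = 0.868 with an estimated correlation). No member passed over all genes, and Tgfb1, which encodes the cytokine TGF-beta 1, rose when adjusted over the list alone (0.56, SE 0.08), while the adhesion protein gene Vcl had 0.24 and the YAP target Ccn2 had -0.26. The size of this shift depended on single arrays. The list's mean minus that of other genes was 0.089 over all arrays, 0.124 without control replicate 1 and 0.145 without Ctcfl replicate 1. It was 0.053 without control replicate 2 and 0.032 without Ctcfl replicate 2, where the list lost its call. Another division of the arrays, which mixes the groups, gave the list a median of -0.075, nearly as large in size as the 0.0775 between the groups.

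Genes that bear on CTCF, the germ line and chromatin did not shift as lists. Some of these lists had low values, with means of 4.09 for spermatogonial and meiotic genes, 4.32 for clustered protocadherins and 4.66 for spermatid genes. The lower quartile of the arrays was 4.09 to 4.12. Distance from background was not measured, so a missing shift in those lists says little. CTCF and cohesin machinery had 19 members with a median of 0.04 (adjusted p = 0.472), with the cohesin acetyltransferase Esco1 at 0.31 and the cohesin subunit Stag1 at 0.17. The 19 measured genes earlier tied to CTCFL, such as Gal3st1 (0.23) and Prss50 (0.23), had a median of -0.01 and a mean of 0.00 that differed in sign, with the test on the side of the mean (adjusted p = 0.999). Among 45 spermatogonial and meiotic genes the median was 0.03 (adjusted p = 0.379), and the germ-line cyclin Ccna1 rose when adjusted over the list alone (0.50, SE 0.08), while the synaptonemal complex gene Syce2 had 0.36. Without the dimmest 33.3% of genes, 8 members of that list remained, and their mean minus that of other genes was 0.15, against 0.04 over all members (camera adjusted p = 0.0677). Over all alternatives the list's adjusted p ran from 0.00751 by mixed fry, which tests for change in either direction, to 0.868 by camera with an estimated correlation. The 32 spermatid genes had a median of 0.00 and a mean of -0.02 that differed in sign, with the test on the side of the mean (adjusted p = 0.655), with Hspa1l at -0.32. For 32 imprinted genes the median was -0.01 (adjusted p = 0.640), and Dcn and Dlk1 (-0.62, SE 0.11) fell when adjusted over the list alone. Clustered protocadherins, whose promoter choice depends on CTCF, did not pass (21 members, median -0.06, adjusted p = 0.640), with Pcdhb22 falling when adjusted over the list alone (-0.62, SE 0.08) and Pcdhb14 at -0.39. The 37 Hox genes had a median of 0.01 (adjusted p = 0.736), with Hoxc8 at 0.30 and Hoxa4 at -0.26, and 27 DNA methylation and Polycomb enzymes had a median of -0.04 (adjusted p = 0.395), with Dnmt3l at -0.35 and Cbx8 at -0.24.

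Signalling lists did not pass either. The medians were 0.06 for 27 p53 targets (adjusted p = 0.640), with Tnfrsf23 at 0.34 and Plk3 at 0.23, and 0.03 for 31 interferon response genes (adjusted p = 0.597), with Rtp4 at 0.30 and Irf9 at 0.20. For 25 NF-kB and chemokine genes the median was -0.05 (adjusted p = 0.233), and the monocyte chemokines Ccl7 (-0.58, SE 0.08) and Ccl2 (-0.40, SE 0.09) fell when adjusted over the list alone. The 27 immediate early genes had a median of -0.08 (adjusted p = 0.160), with Egr1 at -0.75 (SE 0.16) and Spry4 at -0.36. The 30 apoptosis regulators had a median of 0.00 and a mean of -0.01 that differed in sign, with the test on the side of the mean (adjusted p = 0.845), with Casp8 at 0.22 and Bak1 at 0.20. Over the 24 lists that were not called, 53 of 644 genes (8.23%) passed an unadjusted p of 0.05 and none passed over all genes.

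Marker genes of other cell types did not separate the groups. Median log2 changes were 0.03 for 20 adipocyte markers (adjusted p = 0.736, Scd1 at -0.24 and Lep at 0.16), 0.05 for 24 skeletal muscle markers (adjusted p = 0.718, Cdh15 at 0.28 and Mef2c at -0.26) and 0.06 for 22 epithelial markers (adjusted p = 0.472, Krt8 at 0.58 and Krt14 at -0.18). The medians were 0.03 for 24 macrophage and blood cell markers (adjusted p = 0.640, Fcer1g at 0.30 and Cd3g at 0.27) and 0.03 for 24 neuronal markers (adjusted p = 0.543, Tubb3 at -0.36 and Syn1 at 0.26). The 19 endothelial markers had a median of -0.02 and a mean of 0.02 that differed in sign, with the test on the side of the mean (adjusted p = 0.640, Cldn5 at 0.20 and Sox17 at 0.18).

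**Figure D3:**
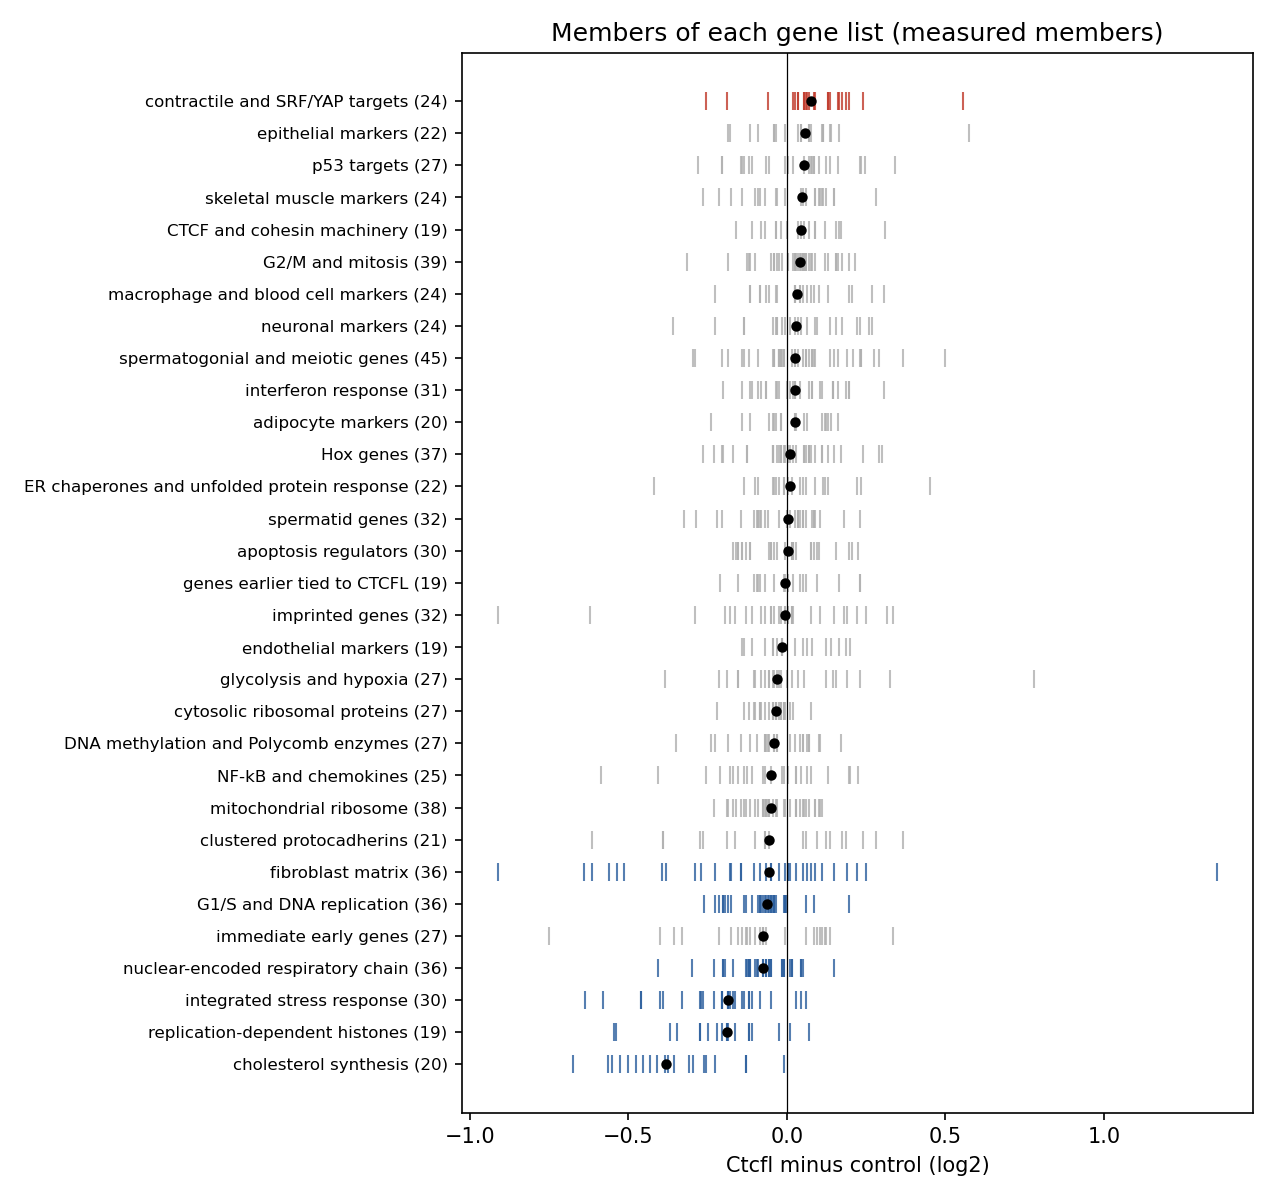
Log2 difference of Ctcfl minus control arrays (x axis) for each measured member (vertical tick) of the 31 gene lists (y axis, number measured in parentheses), with the list median as a black point. Blue lists were shifted lower and the red list higher by camera with a preset correlation, and grey lists were not called; the cholesterol synthesis list has the lowest median, -0.38.

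Because CTCF and CTCFL sites can bound chromatin domains, the positions of changed genes were compared, with gene order from the mouse assembly GRCm38.p6. Of the 9 genes past the threshold, 0 had a next gene that also passed in the same direction. However, 10000 random draws of as many genes gave a mean of only 0.0022 such pairs, so this count could not show whether changed genes have changed neighbours. Lpcat2 and Adgrg1 lie on the same chromosome. Capns2, which neighbours Lpcat2, was at 1.31, while the 36 tested genes between Capns2 and Adgrg1 had a median of -0.04 and none passed, the lowest being Mt2. The collagen gene Col3a1, which lies close to Col5a2, had a log2 change of -0.38.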

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

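Crossed pairing, a fit over all probe sets, an adjusted p under 0.1, lists without called genes and neighbours among genes changed at least 1.5-fold were chosen after seeing the data. The 9 genes that differed between Ctcfl and control arrays (6 higher, 3 lower) were all among the 13 called after quantile normalisation (8 higher, 5 lower), the 9 after median centring, the 9 with the mean of a gene's probe sets, the 20 without the dimmest 33.3% of genes (13 higher, 7 lower) and the 479 with an intensity trend and robust variances (220 higher, 259 lower). All 9 changed at least 1.5-fold, and 20 genes had an adjusted p under 0.1. limma called 0 genes, with 0 higher and 0 lower, with a replicate block (1468 unadjusted), with ordinary t statistics (1940), over all probe sets (1419 with 1 symbol, 1345 with several or none) and without any 1 array (0 to 0, and 1329 to 1663 unadjusted), where fewer residual degrees of freedom remain and the lone array is assumed to vary like the others. The log2 change of the targeted gene Ctcfl was 2.62 with a replicate block, ordinary t statistics and all probe sets, and 2.59 to 2.65 without 1 array, but it lost its call there, with adjusted p-values from 1.52e-13 to 0.649 over all alternatives. Ordinary t statistics rest on only 2 residual degrees of freedom, so their 0 calls say little. Deviations of arrays with the same replicate number had a correlation of -0.10, which gives no sign that the numbers pair the arrays. With 2 arrays per group, this value cannot exclude such pairing. The second principal component, with 30.1% of the variance, set control 1 and Ctcfl 2 against control 2 and Ctcfl 1. With crossed pairing, limma called 0 genes, 0 higher and 0 lower (2105 unadjusted), and 7 lists.

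Of the 7 gene lists, 7 kept their call with both scalings, the filter, the mean of a gene's probe sets, the replicate block and an intensity trend with robust variances, which added cytosolic ribosomal proteins as number 8, and 6 on ranks, where fibroblast matrix was lost. With an estimated correlation camera called 0 lists (2 unadjusted) and directional fry 0 (5 unadjusted). For camera, only 2 residual degrees of freedom then remain, so its 0 calls say little about correlation between members. Mixed fry passed 12, which kept 6 of the 7 and lost cholesterol synthesis (adjusted p = 0.0546), and the cause was not tested. Ordinary t statistics were not tried on the lists. Leaving out 1 array gave 4 to 7 lists: 4 without control replicate 1, 7 without control replicate 2 (cytosolic ribosomal proteins added, contractile genes lost), 7 without Ctcfl replicate 1 (G2/M added, G1/S lost) and 5 without Ctcfl replicate 2. Cholesterol synthesis, the integrated stress response and histones kept theirs without any array. No list median that was called changed sign with scaling, and 7 of the 24 others did with median centring, which moved the median of all genes by 0.03. Among probe sets without a single symbol 0 passed without the dimmest 33.3% (792 unadjusted) and without any 1 array (1155 to 1321 unadjusted), the only alternatives tried for them. Neighbour pairs in which both genes passed numbered 0 within 100 kb and with similar names left out, and there were 2 pairs among genes changed at least 1.5-fold. Over the alternatives tried for single genes, the 8 called genes other than Ctcfl kept their call in 40 values and lost it in 48, the other named genes stayed uncalled in 755 and gained a call in 50, and no call changed direction. How far each probe set lay above background was not measured here.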

Other observations

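The neighbour, doxycycline and single-interval tests and the position of Capns2 were chosen only after the results they bear on were seen, as were the 5 added gene lists, the addition of Gstm5 to 1 of them and the choice to print the bound of the intensity test in place of the percentile of the list. Camera p-values of the added lists were adjusted over those 5 alone, without the 31 fixed lists. Subunits of the v-ATPase, the proton pump that acidifies lysosomes, formed a list that shifted higher. Of 15 measured subunits 14 had higher values, 11 of them in both Ctcfl arrays against both controls, with a median log2 change of 0.15 (camera adjusted p = 1.81e-04, and adjusted p = 0.239 with an estimated correlation). Atp6v1a rose when adjusted over the list alone (0.60, SE 0.08), though not over all genes. Lysosomal enzymes and membrane proteins shifted higher by less, with 21 of 30 higher and a median of 0.07 (camera adjusted p = 0.0243, and adjusted p = 0.423 with an estimated correlation), and the sialidase gene Neu1 rose when adjusted over the list alone (0.46, SE 0.08). These lists were drawn up because Slc29a3 and Rab29 act at lysosomes, and a joint rise of lysosomal genes stays open. Another division of the arrays, which mixes the groups, gave the lysosomal enzymes a median of 0.04, more than 0.5 of their median of 0.07, and the v-ATPase subunits at most 0.01 in size.

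Fatty acid synthesis genes did not pass (17 members, median -0.04, camera adjusted p = 0.205), so a fall beyond the cholesterol branch of lipid synthesis was not detected. Aminoacyl-tRNA synthetases, many of them ATF4 targets, shifted lower, with 13 of 16 lower and a median of -0.06 (camera adjusted p = 0.0337, and adjusted p = 0.423 with an estimated correlation). NRF2 targets and glutathione transferases were drawn up as a list without Gstm5, and the list's call depended on that choice. Its 25 members had a median of -0.05 (camera adjusted p = 0.0458, and adjusted p = 0.423 with an estimated correlation), while with Gstm5 the median was -0.04, the mean 0.04 and the camera adjusted p 0.205. Gsta4 (-0.59, SE 0.09), Mgst1 (-0.50, SE 0.11) and Slc7a11 (-0.46, SE 0.09) fell when adjusted over either version of the list alone. Gstm5 and Gstm7 (0.36, SE 0.10) rose when adjusted over the version with Gstm5 alone. The inhibitor-of-apoptosis relatives Naip5 and Naip6 had log2 changes of 0.78 (SE 0.10) and 0.79 (SE 0.11) and lie next to each other, and probes may not separate them. Among genes changed at least 1.5-fold there were 2 neighbouring pairs with the same direction, Lpcat2 with Capns2 and Naip5 with Naip6, against 0.191 by chance (p = 0.0174, permutation of genes). With pairs of similar names left out, 1 pair remained against 0.160 by chance (p = 0.147, permutation of genes), too few to tell whether changed genes have changed neighbours.

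The lower values of cholesterol synthesis genes were weighed against technical explanations. An intensity-dependent bias would also shift random lists of the same mean level, but their medians had a 2.5th percentile of -0.075 and the list lay at -0.38. A deviation of single arrays would give large medians in the other 2 divisions of the arrays, where the largest was 0.095. Doxycycline in the control medium cannot be told apart from Ctcfl, because 0 arrays separated them. An effect of Ctcfl and an effect of the drug on sterol metabolism both stay open. Whether replicates were separate cultures is not known, so a difference between the cultures of the groups stays open too.

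Genes of the integrated stress response gave the same picture. Matched random lists had a 2.5th percentile of -0.06 against the list's median of -0.18, which argues against an intensity-dependent bias, and the other divisions of the arrays gave at most 0.0125, which argues against a deviation of single arrays. Doxycycline in the control medium cannot be told apart from Ctcfl here either, with 0 arrays that separate them. An effect of Ctcfl and an effect of the drug on these genes both stay open, as does a difference between the cultures of the groups.

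Adgrg1, Lpcat2 and Capns2, all higher and on the same chromosome, raise the question of a regional change. A single change spanning the interval would raise the 36 genes between Capns2 and Adgrg1, whose median was -0.04 with quartiles of -0.18 and 0.09. Capns2 lies inside the Lpcat2 gene in the reference, and its log2 change was lower than that of Lpcat2, with a difference of -0.85 (SE 0.16). That SE treats the genes as independent, although they were read on the same arrays. Both genes had control values below the median of the arrays (4.57 for Capns2, 5.14 for Lpcat2), and their distance from background was not measured. The difference therefore leaves open whether the Capns2 signal comes from transcription of Lpcat2. Separate effects on Lpcat2 and Adgrg1, whether through Ctcfl binding or a vector insertion close to either gene, were not tested.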
